A study of Drosophila melanogaster with 20 samples.

How the data were processed

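Total RNA of dissected Drosophila melanogaster wings was measured on NimbleGen 4-plex arrays in 4 groups of 5: control and Tkv wings of wandering larvae, and control and Tkv wings 24 h after pupa formation. Groups and replicate numbers were taken from the sample titles. The series design text speaks of independently isolated samples of 10 wings. Nothing used here says how the animals of different samples were related beyond that, so p-values measure the spread between these samples.

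The submitters deposited 1 file per array with an intensity per transcript, and the submitters' processing notes name RMA (background correction, normalization and summary of probes). Software versions and settings are not given in the sources used here. The deposited intensity values are linear, above 0 and between 12.2 and 62183, each from 3 to 5 probe pairs per the file headers. A second deposited column, headed as an error, lies between 0 and 1 and rises with intensity. Its unit is not stated, and it was used only to count zeros. The deposited series table holds log2 values equal to the log2 of those intensities to within 5.0e-09, with no further centring. RMA compresses differences near the background, so fold changes of transcripts that are dim in a group are likely to be too small. No detection calls or negative control probes were used here.

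Values were put on the log2 scale. A rule fixed beforehand asked whether any of 5 percentiles (5th, 25th, 50th, 75th and 95th) differed by more than 0.1 between arrays. The medians differed by up to 0.40 and the 25th percentiles by up to 0.21, so the 20 arrays were quantile-normalized together. Quantile normalization assumes equal distributions in all groups, so a shift of all transcripts in 1 direction would not be seen. No transcript was filtered. Tests used limma 3.58.1 in R 4.3.3: lmFit with 4 group means over all 20 arrays (16 residual degrees of freedom), contrasts.fit and eBayes, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over 15473 transcripts. The contrasts were Tkv minus control in larval and in pupal wings, their difference (the interaction), and pupal minus larval in control and in Tkv wings. Files were read with jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. For arrays no depth applies, and the number of arrays limits the precision.

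On simulated arrays with the real means and spreads and 200 changed transcripts, limma recovered 73.1% of 2-fold and 35.8% of 1.5-fold changes in the larval contrast, 76.1% and 37.3% in the pupal contrast, and 52.2% and 14.9% for the interaction, each over 15473 transcripts. For 4-fold changes these shares were 95.5%, 98.5% and 95.5%. No recovered change had the wrong sign, and 11 of 147, 5 of 146 and 6 of 114 calls were false. The simulated noise was normal around the stage means, independent between arrays and transcripts, and drawn once per contrast. It held no slide effect or shared deviation of arrays, so these shares apply to such noise only.

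Transcript IDs were looked up in a RefSeq gene table of the Release 6 assembly. Only 44 of the 15473 IDs occurred in its synonyms, 9 as an entry of their own and the others inside longer synonyms. Of the 44, 17 led to a single symbol and 27 to several, and the latter were not named. The files do not pair the other IDs with genes, and their genome build is not given in the sources used here, so no positions are printed. The naming rule set beforehand (preset genes, the 10 largest rises and falls with a symbol, and members of 37 gene and cell type lists) could therefore not be applied as written. None of the 37 lists had 3 named members, and LanA was the only member named. The 2 largest rises and 2 largest falls per comparison are given by ID, among transcripts that passed the test with the same sign on all 5 slides. All 17 transcripts with a single symbol are described as a group.

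The groups, the tests, the threshold and the alternatives were fixed before the data were examined. Slide and array position were read from the file names. Each slide held 1 array of every group, and the slide followed the replicate number in all groups. Slides were treated as batches, but a slide cannot be told apart from anything else that samples of the same number share. Calls were made on 4 slides and their signs compared on the slide left out. Alternatives were the slide as a fixed or random block, array position with the slide, no further normalization or median centring, the series table, a filter on the dimmest 25% of transcripts, eBayes with trend and robust fitting, fits of the compared groups alone, other thresholds, and leaving out each array or replicate number. No pair of arrays within a group was alike: the lowest median absolute difference of 2 arrays was 0.184 on the log2 scale.

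Several descriptions were chosen after the data had been seen. The boundary of 8.64 between dim and bright is the lowest point of the density of normalized values (bandwidth 0.4). The comparison of responses with the normal stage change was repeated with disjoint slides. A stage score placed each array between the mean larval control (0) and the mean pupal control (1) of the other slides, by projection over all transcripts.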

Results

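Wings dissected from Drosophila melanogaster were profiled on 20 NimbleGen arrays with a single dye, Cy3. The arrays fell into 4 groups of 5, and each array carried total RNA of 10 wings. The groups crossed a developmental stage (wandering larvae of the last instar, or pupae 24 h after pupa formation) with a genotype. Tkv wings expressed an activated form of Thickveins (Tkv), a type I receptor for the BMP-family ligand Decapentaplegic, through the Gal4/UAS system. Control wings came from the matched strain without the UAS transgene, and all animals were moved from 18 to 28 °C for 10 h before dissection. Each array gave an intensity for 15473 transcripts, each read by 3 to 5 probe pairs. The normalized log2 intensities had a dim and a bright mode, parted at 8.64. In control wings 8048 transcripts (52.0%) lay on the bright side on all 5 larval arrays and 7979 (51.6%) on all 5 pupal arrays. The numbers in Tkv wings were 8005 and 7950. The files identify transcripts by FlyBase transcript ID without gene names, and the reference table used here gave a single gene symbol for 17 of them. Other transcripts are described as groups, with the largest changes given by ID. The tkv transcript itself was not looked up, so the transgene was not used as a check of the labels. Any other difference between the Tkv and control strains would enter the comparisons too, at both stages, and cannot be told apart here. A response to activated Tkv below means a difference of Tkv from control wings.

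The first comparison asked which transcripts differed between Tkv and control wings at the larval stage. Relative to larval controls, 113 transcripts were higher and 103 lower in Tkv wings, 1.4% of those tested. The changes were often large. Of the changed transcripts, 48 were higher and 62 lower by at least 2-fold, and 12 were higher and 20 lower by at least 4-fold. The median size among the changed transcripts was 1.01 on the log2 scale. The largest rise was that of FBtr0088591, from 6.65 ± 1.25 in controls to 13.52 ± 0.26 in Tkv wings (log2 intensity, mean ± SD, n = 5), a 116-fold difference (log2 6.86 ± 0.40, SE, limma adjusted p = 8.62e-10). FBtr0073511 rose by 6.74 ± 0.40 (limma adjusted p = 8.62e-10). Among the transcripts that fell, FBtr0079839 went from 10.19 ± 0.10 to 5.85 ± 0.59, a log2 change of -4.34 ± 0.23 (limma adjusted p = 2.38e-10). FBtr0086025 went from 10.68 ± 0.14 to 6.55 ± 0.50, a log2 change of -4.14 ± 0.19 (limma adjusted p = 2.57e-11). The same sign on all 5 slides was a condition for choosing these 4 transcripts. In terms of brightness, 8 of the changed transcripts were dim on all 5 control arrays and bright on all 5 Tkv arrays, and 12 went from bright to dim. Another 86 were bright and 62 dim in both groups. None of the 17 transcripts with a gene symbol passed the limma test, and 1 had an unadjusted p under 0.05.

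When the calls were made on 4 slides, 91.6 to 98.3% of the called transcripts had the same sign on the slide left out. The count fell to 142 without replicate 3 of the larval controls, to 132, 117 and 110 without all arrays of replicate 2, 3 or 5, and to 124 with array position and slide both in the model.

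The second comparison asked the same of the pupal wing. Here 250 transcripts were higher and 239 lower with activated Tkv, 3.2% of those tested. At least 2-fold changes were seen for 117 higher and 94 lower transcripts, and at least 4-fold changes for 20 and 11. The median size among the changed transcripts was 0.88 on the log2 scale. The 2 transcripts with the largest larval rise also led here. FBtr0088591 rose from 5.73 ± 0.46 to 13.58 ± 0.18 (mean ± SD, n = 5), a 232-fold difference (log2 7.86 ± 0.40, SE, limma adjusted p = 1.70e-10), and FBtr0073511 rose by 7.53 ± 0.40 (limma adjusted p = 2.34e-10). The largest fall was that of FBtr0088213, to 5.89 ± 0.45 in Tkv wings, a 34.6-fold difference (log2 -5.11 ± 0.22, limma adjusted p = 1.18e-11). FBtr0078413 changed by -3.57 ± 0.32 (limma adjusted p = 3.53e-07). These 4 were likewise chosen among transcripts with the same sign on all 5 slides. Of the changed transcripts, 20 went from dim to bright and 8 from bright to dim on all arrays of both groups, 249 were bright in both groups and 116 dim in both. None of the 17 named transcripts passed the limma test over all transcripts, and 2 had an unadjusted p under 0.05. Adjusted over the list alone, 1 passed: Fatp1, a fatty acid transport protein, was lower in Tkv wings (log2 -0.43 ± 0.12, limma adjusted p = 0.0463 over the list alone and 0.0693 over all transcripts), with that sign on 5 of 5 slides. That call was lost in 11 of 17 refits, with a highest limma p of 0.179 over the list alone.

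On a slide left out of the calling, 81.4 to 94.0% of the called pupal transcripts had the same sign. The count was 289 when only the pupal arrays entered the fit, and 265 and 306 without all arrays of replicate 3 or 5.

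The study set the larval response against the pupal one, and the third comparison tested that difference as an interaction. The 2 responses overlapped: 45 transcripts were higher and 54 lower at both stages, where independent lists of these lengths would share 1.83 and 1.59. Across the 101 transcripts called at both stages the log2 changes had a Pearson correlation of 0.886. These transcripts were selected on the same changes, which leaves out small values, so that correlation adds no separate evidence. Across all 15473 transcripts the Pearson correlation was 0.375 (Spearman 0.201), with transcripts not being independent replicates. In 100 random reassignments of the arrays within each stage the highest Pearson value was 0.285 and the highest Spearman value 0.300, so the Spearman value lay inside that range. Among the 604 transcripts called at either stage, 467 (77.3%) had the same sign at both.

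The interaction test was passed by 105 transcripts. Of these, 71 had been called in pupal wings only, 16 in larval wings only and 16 at both stages. The response was larger in size in pupal wings for 78 and in larval wings for 27, and its sign was opposite at the 2 stages for 58. FBtr0071612 responded in pupal wings, from 4.99 ± 0.09 to 8.33 ± 0.35, but not in larval wings (log2 -0.29 ± 0.18), a difference between stages of 3.63 ± 0.25 (limma adjusted p = 8.15e-08). FBtr0082315 fell in larval wings, from 8.44 ± 0.25 to 5.10 ± 0.27, and lay at 4.86 ± 0.55 in pupal controls and 4.89 ± 0.34 in pupal Tkv wings (difference 3.36 ± 0.32, limma adjusted p = 4.86e-06). These pupal levels lay near the lowest intensities of the arrays, where a fall could not have been seen. FBtr0071698 rose in larval wings by 2.52 ± 0.22 and changed by -2.43 ± 0.22 in pupal wings, a difference of -4.95 ± 0.32 (limma adjusted p = 3.98e-08). FBtr0081578 rose at both stages, by 4.23 ± 0.15 in larval and 1.20 ± 0.15 in pupal wings (difference -3.03 ± 0.22, limma adjusted p = 8.15e-08). Its pupal control level, 12.68 ± 0.30, was already near the larval Tkv level of 13.20 ± 0.20. Only FBtr0071698 and FBtr0083371, the latter chosen after its values were seen, were called in opposite directions at the 2 stages. FBtr0083371 was higher by 0.53 ± 0.13 in larval wings and changed by -1.15 ± 0.13 in pupal wings (limma adjusted p = 4.73e-05 for the interaction). Its larval call, at a limma adjusted p of 0.0466, was lost in 12 of 17 refits, with a highest p of 0.149. None of the 17 named transcripts passed the limma interaction test, and 1 had an unadjusted p under 0.05.

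**Figure D1:**
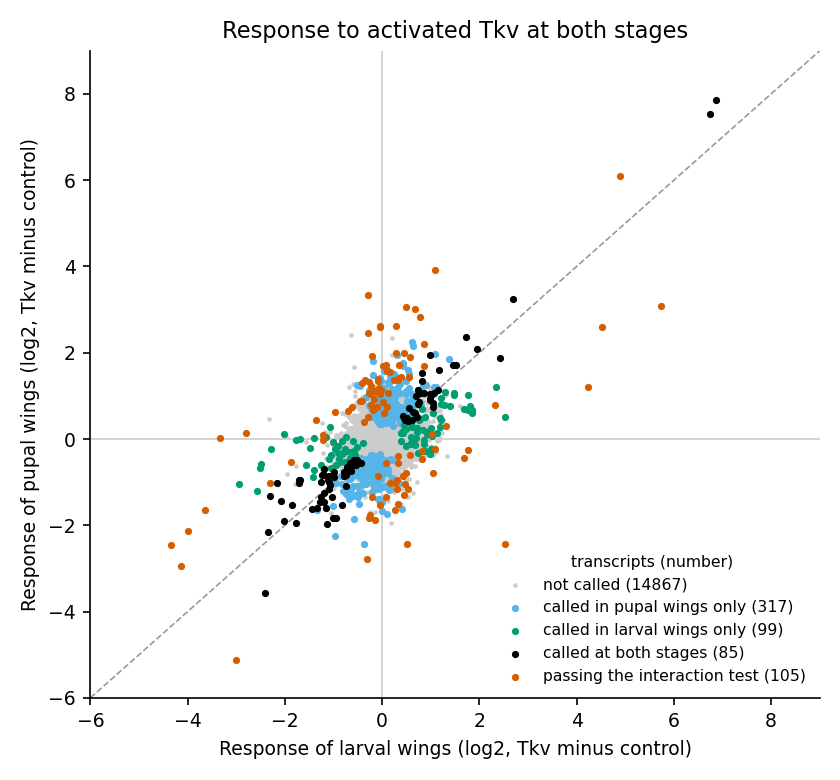
Response to activated Tkv of each transcript in larval wings (x axis) and pupal wings (y axis), as the log2 difference of Tkv minus control group means. Colours separate 317 transcripts called in pupal wings only, 99 in larval wings only and 85 at both stages from the 105 that passed the interaction test, which lie off the dashed line of equal response.

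**Figure D2:**
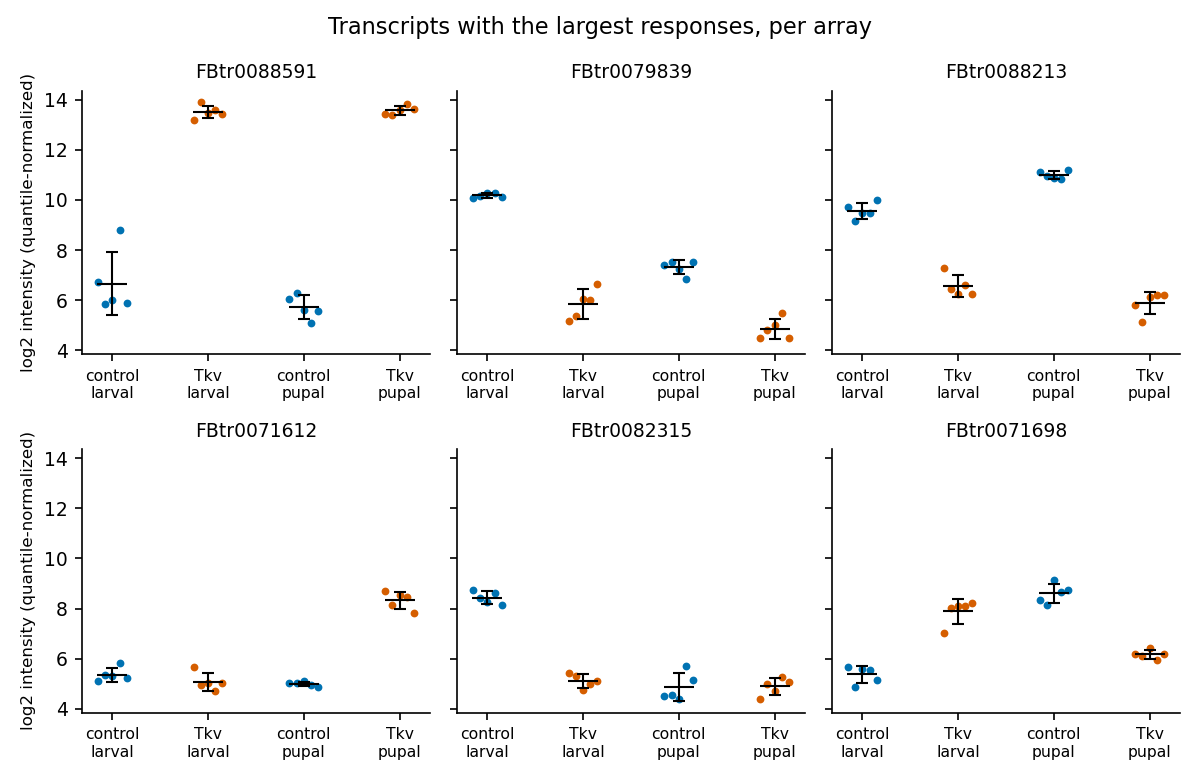
Log2 intensity after quantile normalization of 6 transcripts with large responses or stage differences, in control and Tkv wings at both stages. Points are the 5 arrays of a group and bars the mean and SD; FBtr0071612 reached 8.33 in pupal Tkv wings alone, and FBtr0071698 was higher in Tkv than control wings at the larval stage and lower at the pupal stage.

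Of the transcripts called on 4 slides for the interaction, 91.2 to 100% had the same sign on the slide left out. The count fell to 69 without replicate 3 of the larval controls, to 57, 48, 57 and 62 without all arrays of replicate 2, 3, 4 or 5, and to 66 with array position and slide both in the model.

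The change from larval to pupal stage without the transgene gave the background for these responses. The dissected tissue can hold several cell types, whose marker lists could not be tested. A different make-up of the larval and pupal tissue therefore cannot be told apart from changes within cells, here and wherever the stage change is used below. In control wings 3055 transcripts were higher and 3224 lower at 24 h after pupa formation, 40.6% of those tested. At least 4-fold changes were seen for 611 higher and 473 lower transcripts, 308 went from dim to bright and 223 from bright to dim. FBtr0071744 rose from 6.34 ± 1.13 to 15.47 ± 0.15 (log2 9.13 ± 0.38, SE, limma adjusted p = 2.44e-13), and FBtr0081252 by 9.06 ± 0.56 (limma adjusted p = 6.42e-11). FBtr0086982 went from 13.09 ± 0.20 to 5.75 ± 1.04 (log2 -7.34 ± 0.35, limma adjusted p = 1.29e-12), and FBtr0087917 changed by -6.45 ± 0.64 (limma adjusted p = 6.39e-08). Of the 17 named transcripts, 4 were higher and 6 lower in pupal controls, and 11 passed when adjusted over the list alone. NaPi-III fell most (log2 -4.19 ± 0.23, limma adjusted p = 1.15e-11). LanA, a laminin chain of the basement membrane, fell (log2 -1.64 ± 0.25, limma adjusted p = 1.52e-05), as did fend, sle, mio and the histone deacetylase HDAC3. The 4 that rose were alpha-Spec, a component of the spectrin membrane skeleton (log2 0.52 ± 0.12, limma adjusted p = 0.00156), Fatp1, the kinase gene Dyrk3 and CG16974. The last 3 rose by 0.61 ± 0.12, 0.65 ± 0.15 and 0.64 ± 0.15. Of the transcripts called on 4 slides, 92.7 to 97.7% had the same sign on the slide left out.

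Tkv wings changed between stages much as control wings did. In Tkv wings 2923 transcripts were higher and 3165 lower at the pupal stage. Of the 4943 called in both genotypes, 4929 moved in the same direction, and the 2 stage changes correlated across transcripts with a Pearson value of 0.935. The 2 stage changes share no arrays. Another 1336 transcripts were called in control wings only and 1145 in Tkv wings only, and of these 17 and 16 passed the interaction test. On a slide left out of the calling, 91.0 to 97.4% kept the sign.

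Transcripts that responded to activated Tkv were often also transcripts that changed between stages. Of the 216 larval calls 145 (67.1%), and of the 489 pupal calls 348 (71.2%), were also called for the stage change of control wings, against 40.6% of all transcripts. These comparisons share control arrays. With the response called on 3 slides and the stage change on the other 2, over all 10 such splits, the median shares were 45.3% and 45.2%, against 20.1% of all transcripts. Transcripts with a small spread pass more easily in both lists, also in these splits. The shares were not matched for brightness or spread, so how far this adds to the overlap was not tested. Of the 348 pupal transcripts, 240 (69.0%) moved against the normal stage change: 122 were higher with Tkv and fell with stage, and 118 were lower and rose. Of the 145 larval transcripts 55 (37.9%) moved against it. The difference between these shares was not tested, and the splits below reuse the same arrays. In the splits without shared arrays the opposing share was 52.2 to 75.7% in pupal wings (median 67.6%) and 17.4 to 41.2% in larval wings (median 25.2%). Among transcripts bright on all 20 arrays it was 59.1 to 84.8% in pupal wings (20 to 41 transcripts per split) and 0 to 42.9% in larval wings (3 to 12). Across all transcripts the pupal response and the stage change correlated at -0.208, against -0.106 simulated for unchanged groups sharing the controls, and at -0.157 to -0.0600 without shared arrays. The corresponding covariances were -0.0796 observed and -0.0271 simulated. The larval response and the stage change correlated at 0.0829, against 0.107 simulated, and at -0.0677 to 0.0898 without shared arrays. The larval covariance was 0.0287 observed and 0.0272 simulated.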

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

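The tests of this part were chosen before their results were seen, though the patterns came from the same data. In 8 of 68 groups of 5 arrays examined, 1 value lay far from the other 4, where chance gives about 1 in 20 groups. That rate does not apply to the 3 of these 8 that are counts of zeros. Among the transcripts given by ID, these were FBtr0073511 in larval Tkv wings (12.97 in replicate 2), FBtr0071698 in larval Tkv wings (7.01 in replicate 1), FBtr0081252 in pupal Tkv wings (14.69 in replicate 4) and FBtr0086982 in pupal controls (7.54 in replicate 1), all log2 intensities. The deposited median of replicate 2 of the pupal Tkv wings was low, at 9.19. Zeros in the deposited error column were 53 in replicate 2 and 1 in replicate 5 of the pupal controls, 7 in replicate 4 of the pupal Tkv wings and 1 in replicate 3 of the larval Tkv wings, with none in the other arrays.

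The response to activated Tkv differed between stages by the interaction test for 105 transcripts. The largest such differences (pupal minus larval response, log2) were 3.63 for FBtr0071612, 3.36 for FBtr0082315, -4.95 for FBtr0071698 and -3.03 for FBtr0081578. FBtr0082315 was too dim in pupal controls, at 4.86, for a fall to be seen there. Chance assignment of arrays to groups was tested with 100 splits per comparison, the real one included, and in each comparison only 1 split, the real one, gave as many calls. The highest counts of the other splits were 5 against 216 for larval wings, 18 against 489 for pupal wings, 15 against 105 for the interaction, 6 against 6279 for the stage change of control wings and 2738 against 6088 for that of Tkv wings, the last from splits that exchanged 1 array per group. Chance assignment of arrays across slides is therefore argued against for these counts. Each slide held 1 array of every group, and an exact test that exchanges a pair of groups within slides cannot give a p below 0.0625. That exact test therefore cannot decide on chance within slides. With slide as a fixed block, limma called 255 transcripts for larval wings, 600 for pupal wings and 124 for the interaction. For the stage change of control and Tkv wings it called 6661 and 6461.

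More transcripts passed in pupal than in larval wings, 489 against 216, a ratio of 2.26. Pupal replicates did not spread less, since the pupal over larval ratio of median within-group SDs was 1.08. The fit used a single shared spread per transcript for both contrasts, so a larger pupal spread could itself add pupal calls. That ratio therefore does not settle whether spread contributed. The deviating replicate 2 arrays do not account for the higher pupal count, because without replicate 2 the count ratio was 2.86. The variance of the log2 changes beyond sampling error was larger in pupal wings in all 5 fits that left out a replicate number. The lowest pupal over larval ratio was 1.30. Called changes of at least 2-fold numbered 117 higher and 94 lower in pupal wings, against 48 and 62 in larval wings. Those of at least 4-fold numbered 20 and 11 against 12 and 20, so pupal wings had more large rises but fewer large falls. The median size among called transcripts was smaller in pupal wings, at 0.88 against 1.01 on the log2 scale. Larger effects at the pupal stage are a candidate explanation, as a hypothesis found on the same data, a difference in staging between pupal Tkv and control wings was not excluded, and with only the compared groups in the fit the counts were 289 and 197.

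The control and Tkv pupal arrays of replicate 2 deviated from their group means in opposite directions, with a correlation of -0.186 across transcripts and deposited medians of 9.59 and 9.19. Swapped labels are argued against by the 50 transcripts with the largest pupal response on the other slides: on a scale from the control mean (0) to the Tkv mean (1), the control array lay at 0.0324 and the Tkv array at 0.966. Noise of dim transcripts is argued against by the brighter 50% of transcripts, where the correlation was -0.394, against -0.134 in the dimmer 50%. What set the arrays apart stays open, and no biological explanation was tested. The pupal count was 452 without the control array, 489 without the Tkv array and 377 without replicate 2 in all groups.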

How the results depend on the processing

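In 482 refits of 26 transcript results given in the report none changed sign or lost its call. Several settings, such as the slide as a block, the series table and the filter on dim transcripts, left the log2 changes as they were. No sign could change in those. All 26 had passed in the main fit, and those given by ID were chosen as its largest changes. Their stability therefore does not speak for weaker calls. Added later, FBtr0083371 kept its pupal and interaction calls, but its larval call was lost in 12 of 17 refits, and that of pupal Fatp1 over the named list in 11 of 17, with the sign kept. Of 150 alternative counts and correlations, 128 lay within 1.5 times the reported count or within the spread of the reported correlation. Those from the series table, which holds the same values, are among them. With slide (replicate) as a fixed block, 255 transcripts passed for larval and 600 for pupal wings, 124 for the interaction, and 6661 and 6461 for the stage change of control and Tkv wings; with a random block the counts were 258, 641, 141, 6641 and 6467. Deviations of same-numbered arrays, which shared a slide, correlated at -0.186 to 0.287 (mean 0.0732), with 13 of 30 pairs over 0.1. The mean for different numbers, -0.0181, is no independent comparison, because deviations from a group mean cancel within the group. Of 20 arrays, 5 correlated best with their own number in every other group. The tie was weak and uneven, so the block is given as an alternative. A joint limma test over all slides was passed by 23 transcripts. Slide 1, which held all arrays of replicate 1, differed from the others in 638 transcripts by limma. Slides 2 to 5 each differed in 0, with 667 to 1381 at an unadjusted p under 0.05. Array position with slide in the model left 124 larval and 66 interaction calls; only the compared groups in the fit left 289 pupal calls. An adjusted p under 0.01 left 105, 254 and 51 larval, pupal and interaction calls, by its construction. Leaving out single arrays or replicate numbers gave 110 to 199 larval, 265 to 489 pupal and 48 to 107 interaction calls, and 0.299 to 0.366 for the correlation of the responses. That correlation was 0.416 without the dimmest 25% of transcripts. Over transcripts called at either stage, which were selected on the same changes, it was 0.628. The cause of these shifts was not tested. Quantile normalization is the reported setting, and the series table gave the same calls. The gene list tests were not run, because no list had 3 named members. No detection limit was used, so dim transcripts are the least certain.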

Other observations

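The stage score was chosen after the responses had been seen, and its tests before their results were seen; the alternatives of the score, the test within slides included, were added later. Pupal Tkv wings lay nearer the larval state than pupal controls on the axis of normal stage change, at 0.927 ± 0.023 against 0.973 ± 0.023 (SD, n = 5), a difference of -0.0454 (two-sided exact permutation p = 0.0159; the smallest possible is 0.00794). That test exchanged labels across slides; within slides the difference was below 0 in 5 of 5, from -0.104 to -0.0197, and the exact p was 0.0625, the smallest possible, so chance is not excluded. The arrays scored were not in their own axis, and the difference stayed below 0 with each of 10 pupal arrays left out, at most -0.0360. Across slides the exact p was 0.0635 and 0.0556 without replicate 1 or 3 of the pupal controls (differences of -0.0407 and -0.0371), and 0.0556 on the deposited values (-0.0427). Without the transcripts called in either response the scores were 0.936 ± 0.025 and 0.971 ± 0.021 (SD, n = 5), a difference of -0.0349 (exact permutation p = 0.0556), so whether those transcripts carry it cannot be told apart from a small lag of Tkv pupae in development, a hypothesis that staging Tkv and control pupae by their morphology at several ages could test.

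In larval wings the scores of Tkv and control wings were 0.0290 ± 0.0255 and 0.0220 ± 0.0104 (SD, n = 5), a difference of 0.00698 (two-sided exact permutation p = 0.635 across slides and 0.875 within slides).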
